A study of Mus musculus with 5 samples.

How the data were processed

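The data were 5 libraries of poly(A) RNA from mandibular tissue of mouse embryos at embryonic day 10.5, 3 of controls and 2 of dCKO embryos, grouped by the sample titles and genotypes in the labels. Per the labels' protocols, the tissue was dissected in buffered saline, total RNA was treated with DNase, poly(A) RNA was purified and libraries were made with the Ion Total RNA-Seq v2 kit. The authors deposited a table of raw read counts per gene symbol, whole numbers with a different total in each library. Per the submitters' processing notes, HTSeq 0.5.4p3, DESeq 1.16.0 and the mm9 build were used. The aligner, the annotation, the counting mode and the use of strand are not given in the sources used here, so reads of overlapping or antisense genes could not be told apart. The authors also deposited a table of their own comparison, which per the file headers holds a signal per gene (the mean of normalized counts over all libraries, over wild type and over dCKO), the fold change as a ratio of those means, its log2 value, and a p-value and adjusted p-value. The settings behind these deposited fold changes and p-values are not given in the sources used here. The count columns are headed wild type with a replicate number where the titles say control, and they were matched on the replicate number.

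The count table has 23441 gene rows, of which 27 carry symbols that a spreadsheet turned into dates, and none of these is named here. The authors' table holds 18610 genes and a row for reads in no gene, which takes 41.9% of its mean normalized counts. The count table has no such row. Library totals ran from 6491137 to 13298973 counts, and both dCKO libraries were deeper than any control. Pairs of libraries of 1 group differed by more than sampling noise (chi-square per gene of 4.43 to 14.1), so all 5 were kept as separate samples.

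Counts were analysed with R 4.3.3 and edgeR 4.0.16. Genes with too few counts were removed with filterByExpr at its defaults (minimum count 10, minimum total count 15), which left 12710 genes. Library sizes were scaled with TMM, and dCKO was compared with control by the quasi-likelihood F test (glmQLFit and glmQLFTest, two-sided), with Benjamini-Hochberg adjustment over all genes and a threshold of 0.05. An edgeR adjusted p in the text is from this test. CPM values are TMM-scaled, and are given as the mean and SD of each group. Standard errors of log2 fold changes were derived from the same test, as the absolute log2 fold change over the square root of the F statistic. Lists of genes were tested with camera (limma 3.58.1) on log2 CPM with its preset inter-gene correlation of 0.01 and Benjamini-Hochberg adjustment over 25 lists, each with at least 5 measured members. The 25 lists cover YAP and TAZ targets, Hippo and TEAD components, smooth muscle, pericytes, neural crest mesenchyme, mandibular patterning, BMP, TGF-beta, WNT, FGF-ERK, Hedgehog and Notch signalling, proliferation, p53 and apoptosis, fibrillar matrix, endothelium, erythroid, myeloid, epithelial, mesodermal, cardiac and neural or glial cells, hypoxia and glycolysis, immediate early genes and sex-linked genes. Members shared by lists are counted in each. The lists, the tests and most alternatives were fixed before the data were examined. A further 7 lists were drawn up after the data had been seen, their camera p adjusted over the 6 of them with at least 5 measured members, and are used among the other observations, the megakaryocyte and platelet list also beside the smooth muscle and patterning genes.

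The genes named in the text were set by a rule: Yap1 and Wwtr1, the 10 genes with the largest fold in each direction among those past the threshold, averaging at least 5 CPM and with groups that do not overlap, up to 4 members of each list with the smallest p, and the sex-linked and most abundant erythroid genes. Named outside this rule, after their values were seen, were Cyr61, Ajuba, Hbb-y, Gata1, Klf1, Pf4, Itga2b, Hspa1b, Csf2rb, Sparcl1, Rps13, Dlx3, Dlx5, Hand1, Twist1, Msx1, Sox9, Pdgfra, Tfap2b, Tpm1, Cnn2, Csrp1, Flna and Synpo2, as well as all genes given only among the other observations. Single values of a few genes that the rule or the added lists cover are not reported here. A fold against a group at 0 counts was computed against a floor of 3 counts over the control group. Genomic coordinates are not printed, because the reference in use (GRCm38, GENCODE M21) is another build than mm9. That reference served only for the GC content of each gene's longest transcript, found for 99.3% of the tested genes.

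The alternatives were RLE scaling, the DESeq2 1.42.0 Wald test, limma-voom, no filter on low counts beyond 1 count in all, a stricter filter (1 CPM in 2 libraries and a mean of 5 CPM), each library left out in turn, the replicate number as a block, and for lists also an estimated correlation and the rotation test fry. Where a dCKO library was left out, the lone remaining one was taken to vary like the controls. Alternatives chosen after seeing the data were the removal of each library's trend of expression with GC content (a lowess curve with a span of 0.3), the same removal without control replicate 3, a term for whether a library carried Xist or Y-linked counts, thinning of all libraries to 6491137 counts, and leaving out the embryonic globins. Intervals for the share of counts are 95% Wilson intervals. The tests were tested on simulated data for dCKO against control over 12710 genes, with 100 genes changed per fold size: 84% were recovered at 2-fold and 100% at 4-fold, 7.54% of calls were unchanged genes, and 0 of 40 unchanged lists were called. Genes were simulated independently of each other, so the 0 of 40 does not cover lists whose members vary together. The counts behind these rates were simulated without a trend with GC content, which the deposited libraries carry. The 7.54% is therefore not an error rate for calls made under that trend. The changed genes were drawn from those with an expected count of at least 20, so recovery below that was not tested. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.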

Results

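Poly(A) RNA from the mandibular tissue of mouse embryos at embryonic day 10.5 was sequenced in 5 libraries. The 3 control libraries carried floxed Yap and Taz alleles with no Cre named. The 2 dCKO libraries carried the same alleles together with Wnt1Cre, a Cre driver active in the premigratory neural crest, whose cells form most of the mesenchyme of the first pharyngeal arch. Yap1 and Wwtr1, the gene symbol of Taz, encode transcriptional coactivators of the Hippo pathway that act through TEAD factors. The controls were of the 129SvEv background and the dCKO embryos of C57BL/6J x CBA/J; 129SvEv, so that strain background and genotype could not be separated. Total counts were 7439419, 7190780 and 6491137 in control replicates 1, 2 and 3, and 11346480 and 13298973 in dCKO replicates 1 and 2. Nothing in the labels says that the libraries came from separate embryos, so p-values measure only the spread between these samples, part of which may be technical. The study's title concerns Yap and Taz in the neural crest and the development of smooth muscle, and the single comparison its design states is the mRNA level in dCKO against control mandibular tissue.

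Both targeted genes were lower in each dCKO library than in any control library. Yap1 measured 433 ± 107 CPM (scaled counts, SD, n = 3) in control and 172 ± 3.30 CPM (SD, n = 2) in dCKO tissue, a log2 fold change of −1.33 (SE 0.16, edgeR adjusted p = 1.31e-05). Wwtr1 measured 56.5 ± 15.7 CPM (SD, n = 3) in control and 22.8 ± 0.06 CPM (SD, n = 2) in dCKO tissue, a log2 fold change of −1.31 (SE 0.20, edgeR adjusted p = 1.56e-04). The counts covered whole genes, and which exons are floxed is not given in the sources used here. The question of whether known YAP and TAZ target genes followed was addressed with a list of 22, of which 21 were measured. Ctgf, a matricellular growth factor gene, fell from 42.6 ± 9.69 to 19.2 ± 2.25 CPM (SD, n = 3 and 2), a log2 fold change of −1.14 (SE 0.19, edgeR adjusted p = 4.42e-04). Lats2, which encodes a kinase that phosphorylates YAP and TAZ, and Amotl2, which encodes a motin protein, fell by 0.85 and 0.60 on the log2 scale. Crim1 rose by 0.56, and the other 17 members did not pass the test, among them Cyr61 with 19.2 ± 1.31 and 17.1 ± 2.71 CPM. The same 3 lower and 1 higher members passed when p was adjusted over the list alone. After each library's trend of expression with GC content was removed, 4 passed as lower and 1 as higher. Ajuba was the added lower member (log2 fold change −0.50, SE 0.11, edgeR adjusted p = 0.0144). The median log2 fold change of the list was −0.02, and the list as a whole did not stand apart from other genes in either direction (camera adjusted p = 0.891). Of 20 measured Hippo pathway and TEAD components, Wwc2 and Sav1 fell by 0.54 and 0.49 on the log2 scale and Tead3 rose by 0.52, also when p was adjusted over the list alone (camera adjusted p = 0.412 for the list). Several of these calls were lost with fewer libraries. With single libraries left out, log2 fold changes ranged from −1.01 to −0.69 for Lats2, −0.73 to −0.40 for Amotl2, 0.52 to 0.62 for Crim1, −0.60 to −0.42 for Sav1, 0.44 to 0.64 for Tead3 and −0.61 to −0.47 for Wwc2. Lats2 lost its call without dCKO replicate 1 (edgeR adjusted p = 0.0772), Amotl2 without control replicate 3 or either dCKO library (up to 0.312). Crim1, Sav1 and Tead3 lost theirs without any 1 library other than control replicate 3 (up to 0.171, 0.28 and 0.298). Sav1 and Tead3 also lost theirs when each library's trend of expression with GC content was removed (0.101 and 0.177), at log2 fold changes of −0.30 (SE 0.10) and 0.30 (SE 0.12). Wwc2 lost its call without control replicate 2, dCKO replicate 1 or dCKO replicate 2 (up to 0.179).

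**Figure D1:**
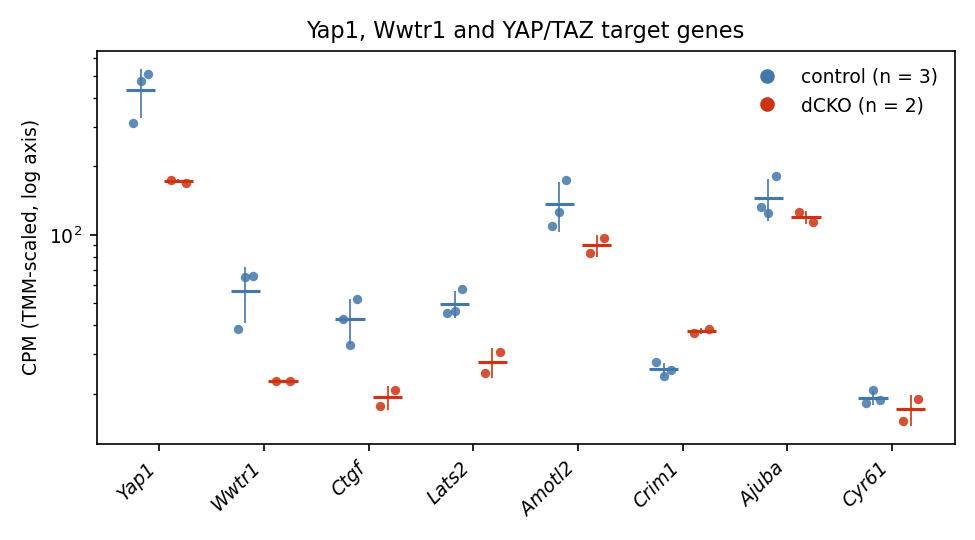
Expression in CPM (log axis) of Yap1, Wwtr1 and 6 members of the YAP and TAZ target list, with 1 point per library, the group mean as a horizontal bar and the SD as a vertical line (control, n = 3; dCKO, n = 2). Both dCKO libraries lie below every control for Yap1, Wwtr1, Ctgf, Lats2 and Amotl2 and above every control for Crim1, while Cyr61 measured 19.2 CPM in control and 17.1 CPM in dCKO tissue.

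Of the 25 lists fixed beforehand, that of red blood cells had the largest median change, and its transcripts were many times more abundant in both dCKO libraries. Of 12 measured erythroid genes, 12 rose, with a median log2 fold change of 4.004. The embryonic globins Hba-x and Hbb-bh1 rose from 2243 ± 370 to 36400 ± 7999 CPM and from 643.5 ± 83.2 to 11760 ± 2415 CPM (SD, n = 3 and 2). Slc4a1, the red cell anion exchanger, rose 22.4-fold and Alas2, the first enzyme of haem synthesis in red cells, 15.9-fold. The erythroid transcription factor genes Gata1 and Klf1, named after their values were seen, rose 19.0-fold and 12.2-fold. Together, the embryonic globins Hba-x, Hbb-y and Hbb-bh1 took 0.377% ± 0.057 (SD, n = 3) of all counts in the controls and 6.36% ± 1.51 (SD, n = 2) in dCKO tissue, a ratio of 16.9. Single libraries ranged from 0.335% (95% Wilson interval 0.33 to 0.339) in control replicate 3 to 0.441% (0.436 to 0.446) in control replicate 1, against 5.30% (5.29 to 5.31) and 7.43% (7.42 to 7.45) in the dCKO libraries, intervals that cover counting error only. The erythroid list stood apart from other genes (camera adjusted p = 1.19e-22), with all 12 also passing when adjusted over the list alone. Its adjusted p was 0.378 with an estimated correlation. That correlation was estimated from 5 libraries, and even this list had an unadjusted camera p of 0.0151 there. No list fixed beforehand passed in that setting. Its values, given here and below, therefore cannot decide whether one of those lists moved.

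Across all 12710 genes tested, 816 differed between dCKO and control tissue, 636 of them higher and 180 lower in dCKO (edgeR's quasi-likelihood test, Benjamini-Hochberg adjusted p below 0.05). The groups did not overlap in 813 of the 816, the exceptions being Sparcl1, Rps13 and Myl2, where chance alone gives 20% of genes and 37.6% of all tested genes did so. Among the higher genes 211 changed at least 4-fold, whereas 24 of the lower genes changed at least 2-fold. The 10 higher genes with the largest folds among those averaging at least 5 CPM were Csf2rb2, Hbb-bh2, Icam4, Slc38a5, Nfe2, Hspa1a, Adra2b, 1300017J02Rik, Rhag and Pkhd1l1, with log2 fold changes from 5.63 down to 4.57. Csf2rb2 and Hbb-bh2 reached at most 0.676 and 0.541 CPM in a control. With single libraries left out, their log2 fold changes ranged from 5.04 to 7.43 and from 5.19 to 6.45. Several of the 10 genes are known from blood cells. Nfe2, a transcription factor of erythroid and megakaryocytic cells, rose from 1.501 ± 0.67 to 41.1 ± 1.31 CPM, Rhag, the Rh-associated glycoprotein of red cells, from 1.78 ± 0.64 to 44.1 ± 0.01 CPM, and Icam4, a red cell adhesion molecule, from 0.274 ± 0.127 to 13.2 ± 1.92 CPM (SD, n = 3 and 2). Hspa1a, a heat-inducible chaperone gene, rose from 1.48 ± 0.84 to 37.9 ± 3.42 CPM. Hspa1a and Hspa1b, Csf2rb2 and Csf2rb, and the beta-globin genes are close copies whose reads the authors' counting could have split, so their single values are uncertain. The 10 lower genes with the largest folds were Col8a2, Fbln5, Mylk3, Radil, Smoc2, Foxc1, Gsc, Scarf2, Yap1 and Ildr2. Col8a2, a collagen VIII chain, fell from 30.0 ± 7.63 to 7.20 ± 0.01 CPM, Fbln5, an elastic fibre protein, from 27.6 ± 7.43 to 7.03 ± 0.01 CPM, and Smoc2, a matricellular protein, from 15.7 ± 4.27 to 5.36 ± 1.84 CPM (SD, n = 3 and 2). The number of lower genes depended on which libraries entered the test. It was 63, 97 and 687 without control replicate 1, 2 or 3 and 39 and 79 without dCKO replicate 1 or 2, with 485, 634, 1637, 442 and 483 genes changed in all. Radil lost its call without dCKO replicate 1 (edgeR adjusted p = 0.054) and Ildr2 lost it without control replicate 2 or 3 or dCKO replicate 1 (up to 0.393).

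**Figure D2:**
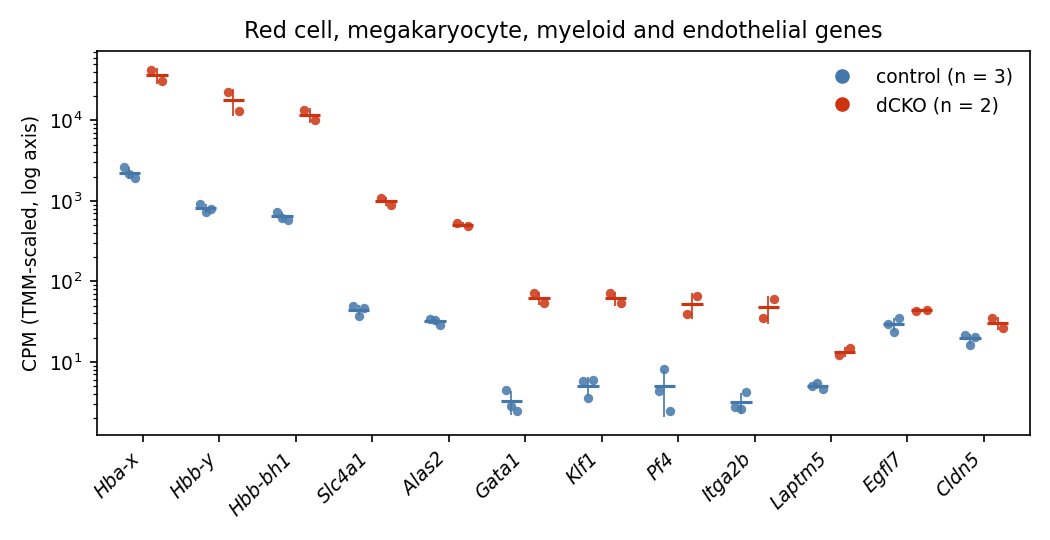
Expression in CPM (log axis) of genes of red cells (Hba-x to Klf1), megakaryocytes (Pf4, Itga2b), myeloid cells (Laptm5) and endothelium (Egfl7, Cldn5), with 1 point per library, the group mean as a horizontal bar and the SD as a vertical line (control, n = 3; dCKO, n = 2). The 7 red cell genes lie 12.2-fold to 22.4-fold higher in dCKO tissue, while Egfl7 and Cldn5 lie 1.49-fold and 1.56-fold higher.

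Genes that pattern the lower jaw were on balance lower in dCKO tissue. The dCKO libraries had 16.9 times the globin share of the controls, and all 10 measured megakaryocyte and platelet genes were higher in them (median log2 fold change 3.34). Of these 10, 5 averaged at least 1 CPM in the controls, and the list was drawn up after the data were seen. The list of immediate early genes was called higher, with 3 of 14 members called (median 0.81). With an estimated correlation the adjusted p of these 2 lists was 0.0823 and 0.519. Of 19 measured mandibular patterning genes, 4 fell and 1 rose (camera adjusted p = 0.0302, median log2 fold change −0.20). The list's adjusted p was 0.519 with an estimated correlation, and 5 members were lower and 1 higher when adjusted over the list alone, the fifth lower one being Dlx3, which also passed over all genes after the GC trend was removed (log2 fold change −0.63, SE 0.12, edgeR adjusted p = 0.00289). Gsc, a homeobox gene of the arch mesenchyme, fell from 16.5 ± 5.98 to 6.01 ± 1.57 CPM, a log2 fold change of −1.44 (SE 0.29, edgeR adjusted p = 0.00336). Dlx6, a distal-less homeobox gene that acts in lower jaw identity, fell from 73.8 ± 7.45 to 43.5 ± 1.81 CPM, and Foxd1 from 28.2 ± 7.65 to 15.4 ± 3.05 CPM (SD, n = 3 and 2). Dlx5, named after its values were seen, fell from 171.3 ± 9.22 to 126.4 ± 7.35 CPM. Alx4 rose from 122.3 ± 8.07 to 170.3 ± 8.09 CPM, a log2 fold change of 0.48 (SE 0.12), and stood 0.34 higher (SE 0.10) after the GC trend was removed, where it did not pass (edgeR adjusted p = 0.0573). Hand1 measured 87.9, 91.6 and 5.50 CPM in control replicates 1, 2 and 3, against 70.1 and 84.0 CPM in dCKO tissue, and did not pass the test. The 21 measured genes of cranial neural crest mesenchyme went both ways. Foxc1, a forkhead factor of the cranial mesenchyme, fell from 36.1 ± 6.40 to 12.7 ± 3.0 CPM, a log2 fold change of −1.503 (SE 0.20, edgeR adjusted p = 4.12e-05), and Prrx1 fell from 654.1 ± 69.7 to 490.5 ± 66.0 CPM. Alx4 rose as given above, while 17 members did not pass, Twist1 (304.3 ± 32.0 and 326.6 ± 61.7 CPM), Msx1 and Sox9 among them. The list did not stand apart from other genes in either direction (camera adjusted p = 0.840), and 3 members were higher and 3 lower when adjusted over the list alone, Tfap2b and Pdgfra being added. The patterning list lost its call without control replicate 3 or dCKO replicate 1 (camera adjusted p = 0.119 and 0.208), as did Gsc without dCKO replicate 1 (edgeR adjusted p = 0.0943) and Foxd1 without control replicate 3 or dCKO replicate 1 (0.0556 and 0.285). Prrx1 did not pass after the GC trend was removed (log2 fold change −0.28, SE 0.10, edgeR adjusted p = 0.152), nor without control replicate 1 or dCKO replicate 1 (0.261 and 0.433), and Alx4 not without control replicate 1 or 2 or either dCKO library (up to 0.131).

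**Figure D3:**
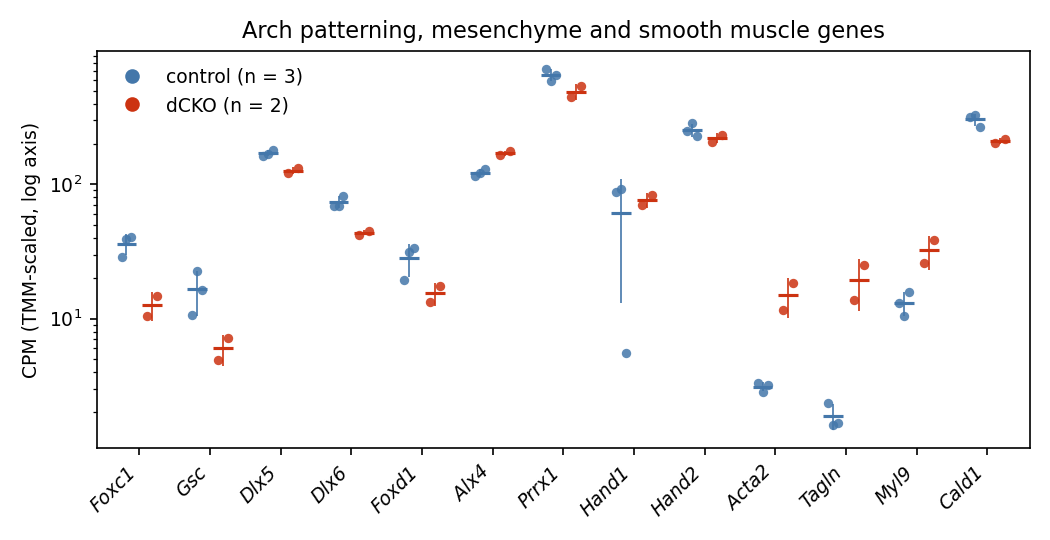
Expression in CPM (log axis) of genes of mandibular patterning, neural crest mesenchyme and smooth muscle, with 1 point per library, the group mean as a horizontal bar and the SD as a vertical line (control, n = 3; dCKO, n = 2). Foxc1, Gsc, Dlx5, Dlx6 and Foxd1 lie lower and Acta2, Tagln and Myl9 higher in both dCKO libraries, and Hand1 in control replicate 3 lies at 5.50 CPM against 87.9 and 91.6 CPM in the other controls.

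Smooth muscle contractile genes, the subject of the study's title, did not move as 1 group. In the same dCKO libraries the globin share was 16.9 times that of the controls. All 10 measured megakaryocyte and platelet genes, 5 of which averaged at least 1 CPM in the controls, were higher (median log2 fold change 3.34). That list was drawn up after the data were seen. The list of immediate early genes was also called higher (median 0.81). The adjusted p of these 2 lists was 0.0823 and 0.519 with an estimated correlation. Tagln and Acta2, early markers of smooth muscle, rose from 1.89 ± 0.41 to 19.5 ± 8.08 CPM and from 3.11 ± 0.24 to 15.04 ± 4.93 CPM (SD, n = 3 and 2), log2 fold changes of 3.35 (SE 0.31, edgeR adjusted p = 2.67e-07) and 2.27 (SE 0.28, edgeR adjusted p = 1.35e-05). Myl9, a myosin light chain gene, rose from 13.2 ± 2.74 to 32.2 ± 9.11 CPM. Cald1, which encodes caldesmon and is also expressed outside muscle, fell from 304.5 ± 31.6 to 210.5 ± 10.99 CPM. The remaining 14 of 18 measured members did not pass, with Tpm1 at 335.3 ± 16.3 and 356.7 ± 20.3 CPM and Cnn2 at 210 ± 45.6 and 206.2 ± 2.54 CPM. Adjusted over the list alone, 5 were higher and 2 lower, Csrp1 and Flna being added above and Synpo2 below. The list was called higher (camera adjusted p = 0.0302, median log2 fold change 0.23, adjusted p = 0.519 with an estimated correlation). The call was lost after the GC trend was removed (camera adjusted p = 0.187). That call was also lost without control replicate 1, 2 or 3 or dCKO replicate 2 (0.0812, 0.0508, 0.0604 and 0.109). Tagln, Acta2 and Myl9 passed without any single library, whereas Cald1 did not without control replicate 1 or 2 or dCKO replicate 1 (up to 0.149). Of 9 measured pericyte and mural cell genes, edgeR called 0, as did DESeq2 and limma-voom. An unadjusted p below 0.05 was reached by 2 of them (Heyl and Mcam), against 2738 of all 12710 tested genes. Heyl passed when adjusted over the list alone, and the list was not called (camera adjusted p = 0.566). Of 15 TGF-beta signalling genes, Tgfb1 rose from 16.6 ± 3.02 to 43.7 ± 6.11 CPM and Thbs1, an activator of latent TGF-beta that platelets also carry, from 44.9 ± 12.6 to 109.8 ± 54.5 CPM, also when adjusted over the list alone, and the list was not called (camera adjusted p = 0.419). Thbs1 lost its call without dCKO replicate 2 (edgeR adjusted p = 0.106). Of 22 fibrillar matrix genes, Col6a3 rose from 2.47 ± 0.73 to 7.43 ± 0.32 CPM and Col5a1 by 0.46 on the log2 scale, also when adjusted over the list alone, and the list was not called (camera adjusted p = 0.967). Col6a3 did not pass without dCKO replicate 1 or 2 (0.0549 and 0.0789), nor Col5a1 after removal of the GC trend (log2 fold change 0.24, SE 0.11, edgeR adjusted p = 0.249) or without control replicate 1 or 2 or either dCKO library (up to 0.269).

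The epithelial, arch core mesoderm, myeloid and Notch lists were called higher in dCKO tissue, with medians far below that of the red cell genes, in the libraries with 16.9 times the globin share. Among 17 epithelial genes, the keratins Krt19, Krt8 and Krt18 rose by 0.91, 0.67 and 0.50 on the log2 scale, and 8 were higher when adjusted over the list alone (camera adjusted p = 4.32e-05, median 0.43, adjusted p = 0.519 with an estimated correlation). Of 11 measured genes of arch core mesoderm and skeletal muscle, edgeR and DESeq2 called 0 and limma-voom 1 (Lhx2). An unadjusted p below 0.05 was reached by 4 of the 11, against 2738 of all 12710 tested genes. Tcf21, Lhx2 and Tbx1 were higher when adjusted over the list alone, and the list was called (camera adjusted p = 0.0136, median 0.73, adjusted p = 0.519 with an estimated correlation). Tbx1, a T-box gene of the arch mesoderm, measured 10.6 ± 3.64 and 17.6 ± 3.22 CPM (SD, n = 3 and 2). Of 9 measured myeloid genes, Laptm5 rose from 4.995 ± 0.41 to 13.4 ± 1.83 CPM, and Spi1 and Lyz2 joined it when adjusted over the list alone (camera adjusted p = 0.0178, median 1.04, adjusted p = 0.519 with an estimated correlation). Of 12 Notch signalling genes, the ligand gene Jag2 rose by 0.57 on the log2 scale, and Heyl and Lfng joined it when adjusted over the list alone (camera adjusted p = 0.0331, median 0.42, adjusted p = 0.519 with an estimated correlation). The myeloid call was lost without dCKO replicate 2 or control replicate 3 (0.719 and 0.0604), the mesoderm call without dCKO replicate 1 (0.056), and the Notch call after removal of the GC trend (0.112) and without control replicate 1 or 3 or either dCKO library (up to 0.0812). Of 18 endothelial genes, Egfl7 and Cldn5 rose by 0.57 and 0.64 on the log2 scale, also when adjusted over the list alone. The endothelial list was not called with all libraries (camera adjusted p = 0.108) and was called without dCKO replicate 1 (0.029). Krt8, Krt18, Jag2, Egfl7 and Cldn5 did not pass once the GC trend was removed (edgeR adjusted p = 0.101, 0.26, 0.214, 0.16 and 0.287). Their log2 fold changes were then 0.46, 0.30, 0.29, 0.38 and 0.37 (SE 0.15, 0.14, 0.12, 0.14 and 0.18). With single libraries left out their log2 fold changes ranged from 0.55 to 0.82, 0.37 to 0.62, 0.47 to 0.67, 0.44 to 0.70 and 0.44 to 0.83. Krt8 lost its call without dCKO replicate 2 (0.067), Krt18 without any 1 library other than control replicate 2 (up to 0.364). Jag2 and Cldn5 lost theirs without control replicate 1 or 2 or dCKO replicate 1 (up to 0.251 and 0.442), and Egfl7 lost it without any 1 library other than control replicate 3 (up to 0.19).

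The lists of immediate early genes and of hypoxia and glycolysis genes, followed as signs of handling and oxygen supply, were also called higher in these dCKO libraries. The globin share of these libraries was 16.9 times that of the controls. Of 14 measured immediate early genes, Btg2 rose from 5.38 ± 1.12 to 18.8 ± 0.77 CPM, Egr1 from 1.95 ± 0.36 to 8.57 ± 5.32 CPM and Dusp1 from 14.2 ± 1.37 to 25.4 ± 0.96 CPM (SD, n = 3 and 2). Adjusted over the list alone 8 were higher (camera adjusted p = 1.24e-05, median 0.81, adjusted p = 0.519 with an estimated correlation). Of 15 hypoxia and glycolysis genes, Slc2a1, a glucose transporter gene, rose from 134.3 ± 7.93 to 282.7 ± 18.2 CPM and Ndrg1 from 3.15 ± 1.28 to 13.2 ± 3.05 CPM. The glycolytic genes Tpi1 and Pfkl rose by 0.44 and 0.45 on the log2 scale, and 8 members were higher when adjusted over the list alone (camera adjusted p = 3.50e-04, median 0.41, adjusted p = 0.519 with an estimated correlation). Egr1 and Dusp1 lost their calls without dCKO replicate 2. With single libraries left out, their log2 fold changes ranged from 1.30 to 2.66 and from 0.76 to 0.89. Tpi1 and Pfkl lost their calls after removal of the GC trend (edgeR adjusted p = 0.0544 and 0.177, at log2 fold changes of 0.34 and 0.26, SE 0.10 each). They also lost them without control replicate 1 or 2, or without dCKO replicate 2.

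The other lists were not called, in the same libraries with 16.9 times the globin share in dCKO tissue. Of 16 p53 target and apoptosis genes, Cdkn1a, which encodes the cell cycle inhibitor p21, rose from 16.3 ± 1.94 to 27.3 ± 0.41 CPM, and Bbc3 and Phlda3 by 1.08 and 0.86 on the log2 scale (camera adjusted p = 0.226). Sesn2 also passed when adjusted over the list alone. Cdkn1a, Bbc3 and Phlda3 each lost their calls without any 1 library other than control replicate 3 (edgeR adjusted p up to 0.093, 0.219 and 0.245), and Bbc3 and Phlda3 also after removal of the GC trend (0.106 and 0.122), at log2 fold changes of 0.80 (SE 0.27) and 0.61 (SE 0.21). Of 24 proliferation genes, Mki67 rose by 0.52 on the log2 scale and 23 did not pass, 1 of which (Bub1) was lower when adjusted over the list alone (camera adjusted p = 0.226). The Mki67 call was lost without control replicate 1 or 3 or dCKO replicate 2 (up to 0.348). Of 12 FGF-ERK target genes, Spred1 fell by 0.44 on the log2 scale, and Spry2 and Dusp4 were higher when adjusted over the list alone (camera adjusted p = 0.458). After removal of the GC trend Spry2 passed over all genes (edgeR adjusted p = 0.0166). Spred1 did not pass after that removal (log2 fold change −0.27, SE 0.10, edgeR adjusted p = 0.172) or without control replicate 1 or 2 or dCKO replicate 1 (up to 0.439). Among 13 BMP signalling genes, 12 canonical WNT targets and 10 Hedgehog targets, edgeR, DESeq2 and limma-voom each called 0, also adjusted over the list alone with edgeR (camera adjusted p = 0.967 for each list). At an unadjusted p below 0.05 the counts were 3 (Smad6, Bmp2 and Id3), 2 (Nkd2 and Ccnd1) and 2 (Gas1 and Ptch1). Of all 12710 tested genes, 2738 had an unadjusted p below 0.05. After removal of the GC trend Id3, Nkd2 and Gas1 passed as lower, with log2 fold changes of −0.48, −0.56 and −0.69 (SE 0.13, 0.14 and 0.14, edgeR adjusted p = 0.0363, 0.0240 and 0.0051). Of 8 measured genes of neurons and glia, Sox10, a transcription factor of glia and migrating neural crest, was at 0 counts in all 3 controls and had 59 and 22 counts in the dCKO libraries. Set against a floor of 3 counts over the control group, its mean was at least 25.6-fold higher and dCKO replicate 2 alone at least 12.1-fold higher. The list was not called (camera adjusted p = 0.167). Of 6 cardiac genes, Myl2 was called lower, which rested on control replicate 1 with 28.5 CPM. The other controls measured 0.676 and 2.90 CPM and the dCKO libraries 1.39 and 1.07 CPM. Without control replicate 1 the edgeR adjusted p of Myl2 was 0.789, after removal of the GC trend it was 0.0855 (log2 fold change −3.15, SE 0.99). The cardiac list was not called (camera adjusted p = 0.226). Adjusted over the list alone, Sox10 and Myl2 were again the 1 passing member of each list. The sex-linked genes split both groups. Xist measured 343.3 CPM in control replicate 3 and 414.1 CPM in dCKO replicate 2, against 0, 0 and 1.29 CPM in the other libraries, whose summed Y-linked counts were 119 to 151 CPM against 1.07 and 0.689 CPM. By these values dCKO replicates 1 and 2 did not come from the same embryo, nor did control replicate 3 and either other control. Whether control replicates 1 and 2 shared an embryo cannot be told from them. Between the groups edgeR, DESeq2 and limma-voom called 0 of the 5 sex-linked genes, with 0 at an unadjusted p below 0.05 (camera adjusted p = 0.793 for the list).

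**Figure D4:**
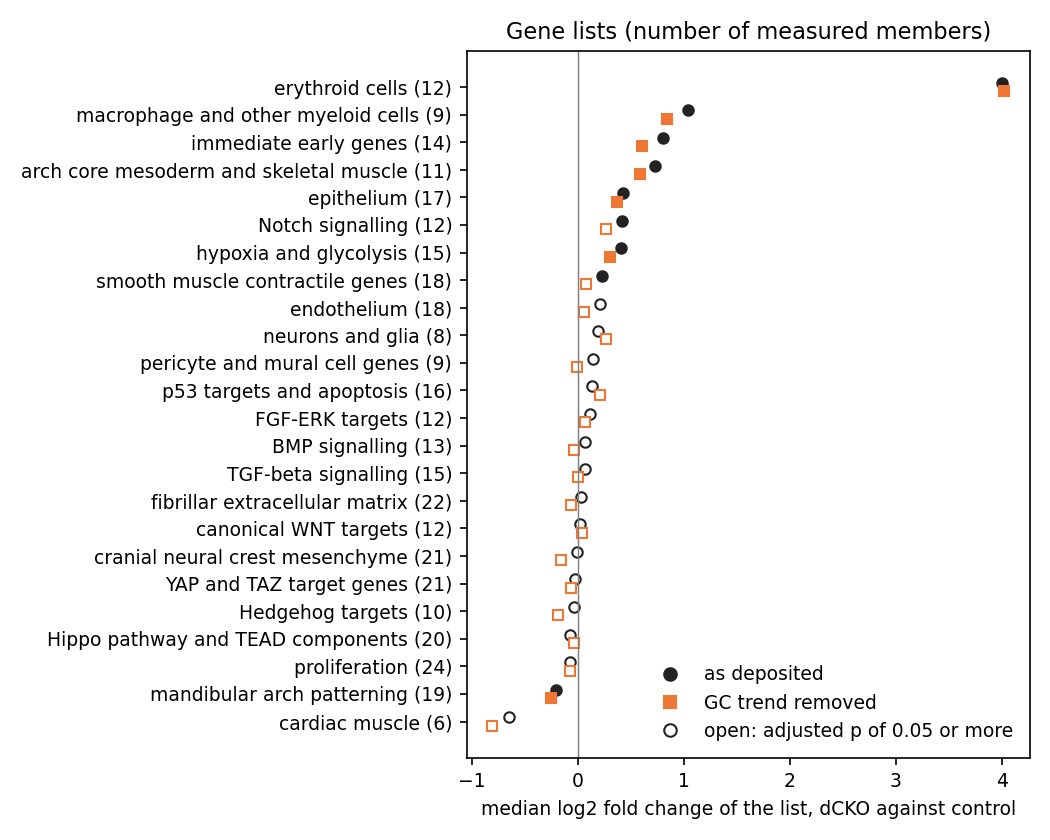
Median log2 fold change (dCKO against control) of 24 gene lists (all but the sex-linked one), with the number of measured members in brackets, for the counts as deposited (circles) and after each library's GC trend was removed (squares), filled where the camera adjusted p is below 0.05. The circle of the erythroid list lies at 4.004 and the circles of the others lie between −0.64 and 1.04, and the smooth muscle and Notch lists are open after the GC trend was removed.

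The fold changes followed the GC content of the transcripts. Across the 12619 genes with a GC value, which are not independent replicates, Spearman's rho between GC content and log2 fold change was 0.481. The median log2 fold change rose from −0.23 in the decile of genes with the lowest GC content to 0.23 in the decile with the highest. The slope of expression against GC content was −0.22, −0.15 and 0.05 log2 units per 10 points of GC in control replicates 1, 2 and 3, and 0.18 and 0.14 in dCKO replicates 1 and 2. After each library's trend was removed, 714 genes passed, 537 higher and 177 lower, of which 487 and 96 were among the genes called without the removal. Yap1, Wwtr1, Ctgf, Foxc1, Gsc, Dlx6, Foxd1, Tagln, Acta2, Myl9 and Tgfb1 all passed after the removal, with log2 fold changes of −1.24, −1.19, −1.12, −1.67, −1.76, −0.75, −0.99, 3.28, 2.28, 1.12 and 1.31.

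**Figure D5:**
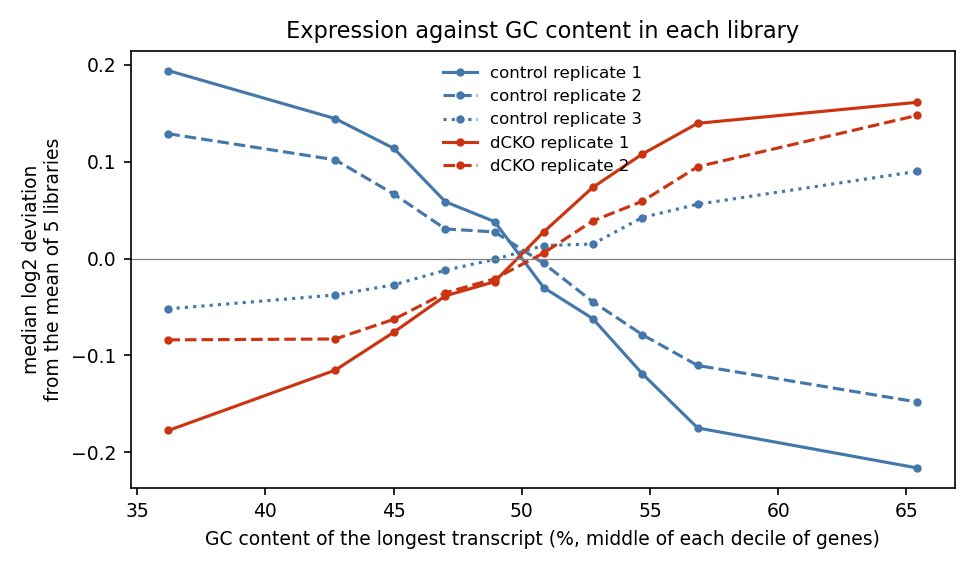
Median deviation of log2 expression from the mean of the 5 libraries (vertical axis, log2) for the genes of each decile of GC content (horizontal axis, percent), with 1 line per library. Control replicates 1 and 2 fall with GC content, both dCKO libraries rise, and control replicate 3 rises slightly, from −0.05 to 0.09.

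The authors' deposited table of the same comparison lists 487 genes higher and 49 lower in dCKO tissue at an adjusted p below 0.05, of which 485 and 49 were among the genes called here in the same direction. In the authors' deposited table the adjusted p was 0.0199 for Yap1, 0.0746 for Wwtr1 and 0.275 for Gsc, and 2.65e-05 for Foxc1. Across the genes tested here, the log2 fold changes of the authors' deposited table and of the fit reported here had a correlation of 0.994.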

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

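The GC trend removal, alone or without control replicate 3, the sex term, the thinning and the removal of the globins were chosen after seeing the data. Yap1 and Wwtr1 stayed lower and past the threshold under all 16 alternatives, with log2 fold changes from −1.51 to −1.06 and from −1.52 to −1.02. The 816 changed genes (636 higher, 180 lower, 77.9% higher) became 442 to 1637 when single libraries were left out, with 403 to 950 higher and 39 to 687 lower. Fewer libraries lower the power, but without control replicate 3 the count rose to 1637 (58.0% higher), and after removal of the GC trend the same omission gave 779 genes, 528 higher and 251 lower (67.8% higher). Without any filter, which tests 18611 genes, 1156 passed and 305 were lower. With the replicate block 2121 genes passed, 1200 higher and 921 lower (56.6% higher), and 632 and 179 of the genes called without it were among them. Control replicate 3 has no dCKO library of its number, so the block absorbs it and the fold changes rest on replicates 1 and 2. The numbers do not pair the samples, since the labels name nothing shared and the within-number deviations correlate at 0.0487 over only 2 pairs. The other alternatives gave 670 to 946 genes, the DESeq2 test 809 with 556 higher and 253 lower. Of the 64 called genes that the naming rule covers besides Yap1 and Wwtr1, 0 reversed under any alternative, while genes named outside the rule were not followed there; 18 lost their calls after GC trend removal (4 uncalled genes of the rule, Id3, Nkd2, Gas1 and Spry2, gained one), 7 with DESeq2 (Tead3, Thbs1, Bbc3, Phlda3, Egfl7, Cldn5 and Myl2), 7 after thinning, and 5 to 24 without a single library.

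The called lists were less stable. With a correlation estimated from 5 libraries, even the erythroid list had an unadjusted camera p of 0.0151, with 12 of 12 members higher. No list fixed beforehand passed in that setting, so it cannot tell lists that moved from those that did not. With an estimated correlation the adjusted p was 0.378 for the erythroid list and 0.519 for the other 8 called lists. With fry, which tests a list against no change rather than against other genes, it was 0.0647 for smooth muscle, epithelium, hypoxia and immediate early genes, 0.0779 for Notch and 0.231 for patterning and myeloid cells. With the DESeq2 statistics it was 0.0551 for patterning, 0.0689 for smooth muscle, 0.138 for myeloid cells and 0.199 for Notch and mesoderm. Without a filter it was 0.0954 for smooth muscle and 0.102 for Notch, with the stricter filter 0.102 for patterning and mesoderm, after thinning 0.0508 for mesoderm and 0.0707 for smooth muscle, and with the replicate block 0.0644 for smooth muscle and Notch and 0.0375 for cardiac muscle, which is not called otherwise. After GC trend removal it was 0.187 for smooth muscle and 0.112 for Notch, and 0.309 and 0.228 when control replicate 3 was also left out. Without single libraries the adjusted p ranged from 0.00857 to 0.109 for smooth muscle, from 0.0237 to 0.0812 for Notch, from 0.00553 to 0.208 for patterning, from 0.00553 to 0.056 for mesoderm, from 3.06e-06 to 0.719 for myeloid cells and from 0.029 to 0.462 for endothelium. The erythroid, epithelial, hypoxia and immediate early lists were called without any single library. Except where a smaller number of libraries or genes is the setting itself, the cause was not tested. At equal depth, 6491137 counts per library, 746 genes passed, and 558 of the higher and 147 of the lower genes called at full depth were among them. The stricter filter left fewer than 5 members of the myeloid, cardiac and neural lists, which have no value there. The form of fry that lets members go both ways gave an adjusted p of 0.0075 for neural crest mesenchyme. It gave 0.0182 for YAP and TAZ targets, Hippo components and fibrillar matrix, and 0.0419 for BMP and Notch. A low value there does not set a list apart from other genes.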

Other observations

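The added gene lists, the tests of vessels, of globins alone, of blood carried over and of GC slopes among the controls, and the Hand1 tests other than GC content were chosen only after the result was seen. Other gene groups of blood cells rose with the erythroid list. All 8 haem synthesis enzymes were higher in dCKO tissue, with a median log2 fold change of 1.78 (camera p adjusted over the 6 testable added lists, here as for the others of these, p = 4.66e-15, and 0.0823 with an estimated correlation). Cpox rose from 45.2 ± 3.13 to 305.9 ± 31.4 CPM (SD, n = 3 and 2). Of 13 red cell membrane genes 12 were higher, with a median of 3.96 (camera adjusted p = 2.93e-24, and 0.0398 with an estimated correlation), Epb4.1 being the exception. Ank1, which encodes red cell ankyrin, rose from 11.3 ± 1.41 to 206.2 ± 4.93 CPM. All 10 measured megakaryocyte and platelet genes were higher as well, with a median of 3.34 (camera adjusted p = 2.35e-11, and 0.0823 with an estimated correlation). Only 5 of them averaged at least 1 CPM in the controls. The filter can keep a gene on the 2 dCKO libraries alone, so for the rest a rise may follow in part from having been measured. Pf4, a platelet chemokine gene, rose from 5.01 ± 2.96 to 52.97 ± 19.1 CPM and Itga2b, the platelet integrin, from 3.20 ± 0.94 to 47.4 ± 18.1 CPM.

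Stress genes gave a mixed picture. Of 11 measured genes of the integrated stress response, Trib3, Ddit3, Ddit4, Atf5 and Shmt2 were higher, Trib3 rising from 2.19 ± 0.73 to 46.2 ± 19.2 CPM and Ddit3 from 5.32 ± 1.68 to 19.6 ± 3.66 CPM (camera adjusted p = 3.98e-04, and 0.198 with an estimated correlation). The metallothioneins Mt1 and Mt2 rose 11.9-fold and 11.1-fold, from 27.9 ± 1.78 to 332.9 ± 6.61 CPM and from 19.5 ± 2.19 to 215.4 ± 12.4 CPM. Among 11 heat shock genes Hspa1a and Hspa1b rose, Hsp90aa1 and Hsph1 fell by 0.39 and 0.41 on the log2 scale (0.25 and 0.35 after the GC trend was removed, edgeR adjusted p = 0.0984 and 0.0454) and 7 did not pass, with 2 higher and 5 lower when adjusted over the list alone, so the list's mean (0.59) and median (−0.12) differ in sign and the list was not called (camera adjusted p = 0.535). Of 18 cholesterol synthesis genes Nsdhl and Idi1 fell by 0.705 and 0.48 on the log2 scale, Idi1 not passing after the GC trend was removed (edgeR adjusted p = 0.134), and the list had a median of −0.21 (camera adjusted p = 3.98e-04, and 0.0823 with an estimated correlation). Single libraries stood apart for a few genes: AI506816 measured 1.76 CPM and Rmrp 3.51 CPM in dCKO replicate 1, against 40.04 to 52.55 and 18.3 to 19.9 CPM in the other libraries, and Pttg1 measured 19.0 CPM in dCKO replicate 2 against 45.2 to 59.4 CPM.

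The first pattern weighed is the rise of red cell transcripts. The tables argue against a bias with GC content, since the list's median log2 fold change was 4.025 after the trend was removed, and against globin reads alone, since the median of the other members was 3.951. They also argue against more vessels that each hold the usual amount of blood, since the highest log2 fold change among endothelial genes was 0.639. More blood in or on the dCKO tissue is a candidate explanation, with the lowest dCKO globin share at 12.0 times the highest control share, but blood held in the tissue and blood carried over at dissection cannot be told apart, as no record of washing is given in the sources used here. Genotype and strain background, which go together in this design, stay open and untested.

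The second pattern is the trend of fold changes with GC content, which bears on the list calls. Slopes among the 3 controls spanned 0.273 log2 units per 10 points of GC, against 0.265 between the groups. Without control replicate 3 they spanned 0.0763 against 0.343. Control replicates 1, 2 and 3 had slopes of −0.2224, −0.1461 and 0.05025 at globin shares of 0.4412%, 0.3555% and 0.3345%. The slope thus rose as the share fell, which argues against blood transcripts as the source of the slopes among the controls. Between the groups, slope and globin share rise together. There a bias between libraries and GC-rich blood transcripts cannot be told apart as the source of the trend. Removing the trend left the calls of immediate early genes, epithelium, hypoxia, mesoderm, myeloid cells and patterning, with camera adjusted p of 1.75e-04, 2.98e-04, 1.53e-04, 0.0182, 0.0182 and 0.00124, which counts against the GC trend as their whole cause. It ended the smooth muscle call (camera adjusted p = 0.187) as the median fell from 0.23 (quartiles 0.04 and 0.68) to 0.08 (−0.09 and 0.57). That is the fall by over 50% set as the prediction of a GC bias. Removing the trend lowers this median whatever the source of the trend, so the fall cannot decide between sources. Tagln, Acta2 and Myl9 were still called higher (log2 fold changes of 3.28, 2.28 and 1.12) and Cald1 lower (−0.42). For Notch (camera adjusted p = 0.112) the median fell from 0.42 (quartiles 0.12 and 0.50) to 0.27 (0.11 and 0.33), by less than 50%, so a GC bias and a difference between the groups cannot be told apart.

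The third pattern is Hand1, a transcription factor gene of the distal arch, at 5.50 CPM in control replicate 3. The tables argue against embryo sex, since in dCKO replicate 2, the other library with high Xist and few Y-linked counts, Hand1 stood at 95.6% of the median of the Y-carrying libraries, and against GC content, since Hand1 stayed 18.01-fold below the lower of the other controls after the trend was removed. A distal arch missing as a whole would lower Hand2 and Alx4 too, but Hand2 was only 1.17-fold below the mean of the other controls and Alx4 was not lower. A smaller part of the arch, or another difference in the tissue taken, may be the source, as 5 genes (Alx1, Bmp5, Hand1, Rgs5 and Syt6) were at least 4-fold below both other controls in that library, among genes averaging 5 CPM and not sex-linked, and 0 in control replicate 1 or 2 on log2 CPM with edgeR's prior count (on plain CPM 1 in each, Csf2rb2 and Myl2). Which tissue differed cannot be told apart from these libraries.

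Among the 10 splits of the 5 libraries into 3 and 2, the real one gave 816 genes and the highest of the others 5, and with 1 split giving as many genes the splits are too few for a share under 0.05.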
